A study of Homo sapiens with 8 samples.

How the data were processed

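The series holds poly-A RNA sequencing of 8 THP-1 foam cell libraries, 4 with vehicle (DMSO) and 4 with 0.5 µM auranofin (AF). Libraries were made from 250 ng of total RNA with an automated stranded poly-A preparation, per the labels' protocols. The authors deposited one table of raw counts per gene, whole numbers with no normalisation. STAR 2.6.1d, featureCounts, Subread 1.6.3 and the GRCh38 build are named per the submitters' processing notes; the annotation, the strand setting and the treatment of multi-mapped and overlapping reads are not given in the sources used here. Each column was matched to its sample by title, and groups and replicate numbers were taken from the titles.

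The counts themselves bear on how reads were assigned. The 4 ribosomal RNA entries with most counts lay between 34616 and 43105 counts in DMSO replicate 3, and between 2011877 and 2384638 in AF replicate 1. Whether multi-mapped reads were counted at each copy was not settled. Of 88 genes with over 90% of their exon bases overlapped by another gene on the same strand, 3 reached a mean of 100 counts, as did 2 of 23 overlapped on the other strand, against 49.6% of the 11531 genes with under 1% overlap. CD68 (3 to 109 counts) had 81.7% of its exon bases overlapped on the same strand and EIF4A1 (0 counts in each library) 48.6%, less than that class. Why they are low was not settled, and they are not interpreted here. RIGI (4 to 15 counts) was low without such an overlap. These 3 genes were named after their values were seen. Values of pseudogenes, paralogs and overlapping or antisense genes are uncertain. Gene positions and exon overlaps were taken from GENCODE 29 on GRCh38, which may differ from the authors' annotation, and 15046 of the tested genes had a position. The table has 62700 rows, of which 20357 are named by an Ensembl ID.

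The counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with its defaults (17535 genes kept), glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The design was drug against vehicle with all 8 libraries and no block, leaving 6 residual degrees of freedom. The standard error of a log2 fold change is its size divided by the square root of its F statistic. CPM were computed from the deposited counts with TMM-scaled library sizes. The biological coefficient of variation was 12.8%. Depth was 19336073 to 32325981 counts per library, and the TMM factor of AF replicate 1 was 0.679, against 1.04 to 1.08 in the other libraries. Errors cover the spread between libraries. No molecular identifiers are described, so counts are not independent molecules.

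Before the data were examined, 30 gene lists (555 entries), the test, the alternatives and the rule for named genes were fixed. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the 30 lists. With a preset correlation 17 lists passed, and with an estimated correlation 2 did, the SREBP2 and interferon lists. With an estimated correlation 0 lists passed when any one library was left out, and with no filter on low counts 1 did, the interferon list. fry, which asks whether the genes of a list move on balance one way, and does not compare them with other genes, was an alternative. Genes were named by 3 parts of a rule. Part 1 took the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, passing over IDs without a symbol. Part 2 took, for each list, the members with the smallest p, up to 3 where the list passed or had at least 3 called members and otherwise 1, plus the called member with the smallest p against the majority. Part 3 took 12 genes whatever their result, among them TXNRD1, HMOX1, ABCA1, ABCG1, CD36, MSR1, SOAT1, PLIN2, IL1B and CCL2. Some genes that the rule names are not reported here. Genes outside the rule are said to be named after their values were seen.

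Library names share stems (A4, A5, A13 and A14), and libraries of a stem were to be summed if their counts agreed within sampling noise, a chi-square per degree of freedom of 1.1 or less. No pair met this: the lowest was 2.96, between DMSO replicates 2 and 3, which have different stems. All 4 libraries per group therefore entered singly. An exploratory fit of the same design was looked at before the final one, and list results and pair values had been seen when the closing section's tests were written.

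Alternatives were DESeq2 1.42.0, other scalings, other filters on low counts, blocks by replicate number or name suffix, summed libraries, limma voom with a correlation within stems, leaving out each library or each stem, and, added after the data were seen, protein-coding genes alone and the division of libraries into 1 and 4 against 2 and 3. The main test was tried on simulated counts for the 17535 genes with 50 genes changed at each of several sizes. It recovered 70% of genes changed 1.5-fold, 90% of those changed 2-fold and 100% of those changed 4-fold, with 8 false among 146 calls, and made 1 call when no gene was changed. Smaller simulated changes were mostly missed. The simulation's calls were far fewer than the 2705 in the data, so its adjusted threshold was stricter and its recovery of small changes may not carry over.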

Results

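Poly-A RNA was sequenced from THP-1 cells, a human monocytic leukaemia line, that had been turned into macrophages with the phorbol ester PMA (50 ng/mL for 72 h) and then loaded with acetylated low-density lipoprotein, which fills macrophages with cholesteryl esters and makes them foam cells. The cells received vehicle (DMSO, below 0.1% by volume) or 0.5 µM auranofin, a gold compound known to inhibit thioredoxin reductase. Per the sample protocol the drug was given for 24 h before the 48 h lipid load and kept on throughout, whereas the series' design text places it after the load. There were 4 DMSO and 4 auranofin (AF) libraries, and the question was how auranofin alters gene expression in foam cells. The deposited gene counts summed to between 19336073 (DMSO replicate 4) and 32325981 (AF replicate 2) per library. AF replicate 1 stood apart: ribosomal RNA, not counting that of mitochondria, made up 34.8% of its counts, against 0.743% to 0.963% in the other 7 libraries, and protein-coding genes 59.4%, against 91.2% to 91.6%. Nothing in the labels says that the libraries came from separate cultures, and several share the stem of their library name, so the p-values measure only the spread between these libraries, which may be technical.

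**Figure D1:**
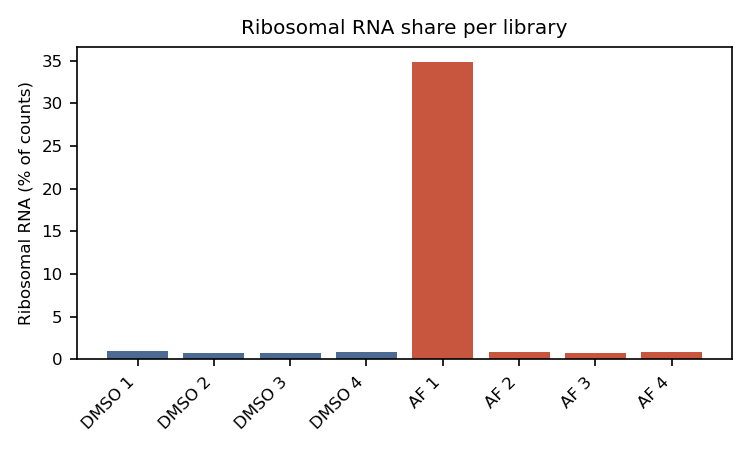
Ribosomal RNA as a percentage of all counts in each library (bars; DMSO blue, auranofin red). AF replicate 1 reached 34.8%, and the other 7 libraries lay between 0.743% and 0.963%.

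Among called genes with a mean of at least 5 CPM and no overlap between the groups, auranofin lowered HLA-DRA, F13A1, ADORA3, C1QC, GABRB2 and AXL most and raised MT2A, BIRC3, EGR1, CXCL8, NR4A2 and MT1X most. HLA-DRA, the alpha chain of an MHC class II molecule, fell from 14.1 ± 0.988 to 1.75 ± 0.306 CPM (normalised counts scaled to library size; mean ± SD, n = 4 per group), a log2 fold change of -2.98 ± 0.13 (SE). F13A1, a coagulation factor subunit made by macrophages, fell by 2.65 ± 0.19 on the log2 scale and C1QC, a chain of complement C1q, by 1.99 ± 0.12. The adenosine receptor gene ADORA3 fell by 2.04 ± 0.28, the GABA receptor subunit gene GABRB2 by 1.62 ± 0.23 and the receptor kinase gene AXL by 1.59 ± 0.15. The metal-binding protein gene MT2A rose from 3.69 ± 1.40 to 24.0 ± 7.50 CPM, a log2 fold change of 2.71 ± 0.25, and its relative MT1X rose by 1.63 ± 0.15. The apoptosis inhibitor gene BIRC3 rose by 1.95 ± 0.31, the chemokine gene CXCL8 by 1.80 ± 0.32, and the transcription factor genes EGR1 and NR4A2 by 1.87 ± 0.21 and 1.77 ± 0.24. Each of these 12 genes had an adjusted p of 0.00154 or less in edgeR's quasi-likelihood test, and its 4 AF values did not overlap its 4 DMSO values. Sizes differed between libraries 1 and 4 of each group and libraries 2 and 3, a division seen in the counts and not in the labels. BIRC3 rose by 0.78 in the first pair alone and 2.93 in the second, and CXCL8 by 0.81 and 2.35, while ADORA3 had log2 fold changes of -1.10 and -3.08 and F13A1 of -1.99 and -3.32. On GRCh38, HLA-DRA (ENSG00000204287.13) spans chromosome 6 from 32439842 to 32445046, F13A1 (ENSG00000124491.15) chromosome 6 from 6144085 to 6321013, MT2A (ENSG00000125148.6) chromosome 16 from 56608199 to 56609497 and CXCL8 (ENSG00000169429.10) chromosome 4 from 73740506 to 73743716. Their counts are summed over exons of the whole gene. Members of the metallothionein and MHC class II families share sequence, so reads may be divided unevenly among them.

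Across the 17535 genes tested, 2705 changed at an adjusted p under 0.05, 1336 higher and 1369 lower with auranofin (edgeR, Benjamini-Hochberg). Of these, 316 changed at least 2-fold, 138 higher and 178 lower. Protein-coding genes made up 195 of the 316, with 67 higher and 128 lower, and the rest were pseudogenes and other or unmatched entries. Summing the libraries that share a name stem gave 2613 genes, and leaving out AF replicate 1 gave 2676, of which 2294 were shared with the full set in direction. Scaling by library totals alone, which the ribosomal RNA of AF replicate 1 enters, gave 883 genes, of which 20.7% were higher against 49.4% with composition factors, and moved the median of all genes by -0.15 on the log2 scale. The count was 1616 without DMSO replicate 2, 1648 without DMSO replicate 3 and 1660 without AF replicate 3. Libraries 1 and 4 of each group alone gave 212 genes and libraries 2 and 3 alone 5354. The first of these fits holds AF replicate 1. The chi-square per degree of freedom was 612 between AF replicates 1 and 4, against 4.49 between AF replicates 2 and 3. A wider spread lowers the number of calls, so these counts do not compare the size of the response.

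**Figure D2:**
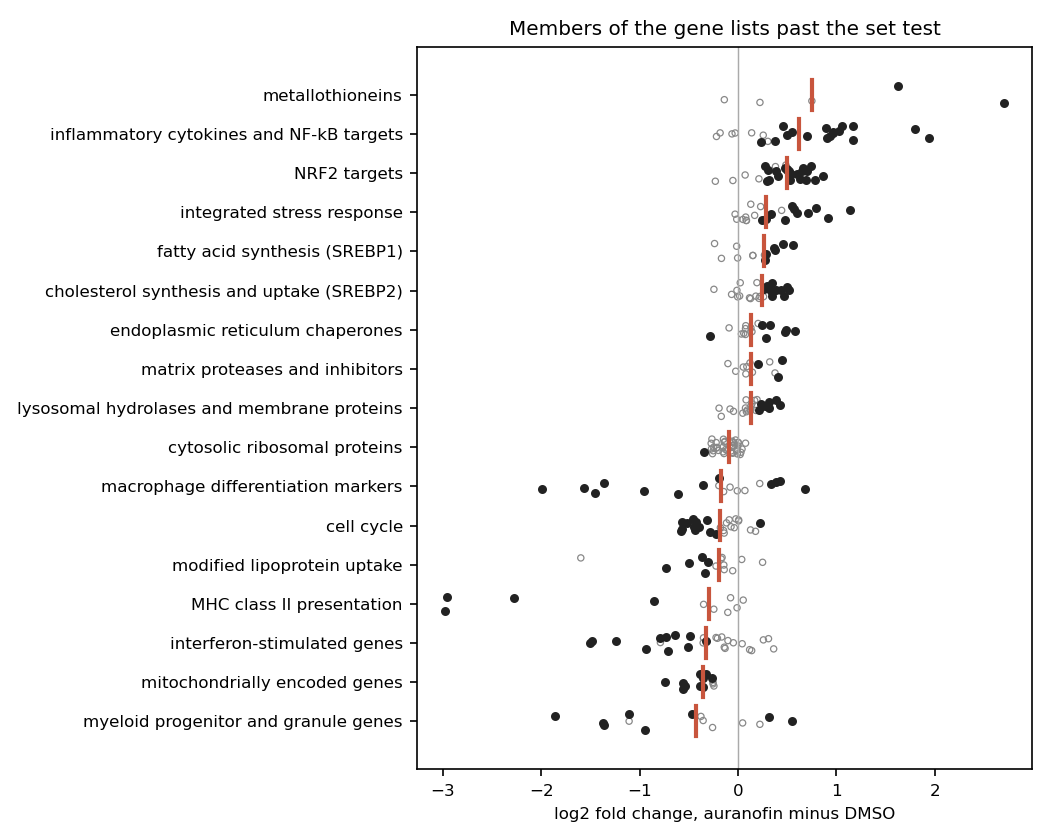
Log2 fold changes (auranofin minus DMSO) of the tested members of the 17 gene lists that passed the set test with a preset correlation, of which 2 passed with an estimated one. Filled points are genes with an adjusted p under 0.05, open points the other members, and red bars the list medians, which were 0.50 for NRF2 targets and -0.32 for interferon-stimulated genes.

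Targets of NRF2, the transcription factor of the oxidative stress response, rose together. Of 27 tested members 21 rose (22 adjusted over the list alone, 21 without AF replicate 1, and 2 with library totals alone), with a median log2 fold change of 0.50 (camera with a preset correlation, adjusted p = 8.5e-13; adjusted p = 0.0995 with an estimated correlation). NQO1, a quinone reductase gene, rose from 103 ± 3.42 to 187 ± 15.8 CPM (log2 fold change 0.86 ± 0.06). The malic enzyme gene ME1 rose by 0.78 ± 0.07, the transporter gene ABCC3 by 0.65 ± 0.07 and the haem oxygenase gene HMOX1 by 0.50 ± 0.08. TXNRD1, which encodes cytosolic thioredoxin reductase, rose by 0.40 ± 0.06, from 225 ± 7.44 to 297 ± 22.3 CPM (adjusted p = 0.00077, edgeR). Of 5 metallothioneins tested, MT2A and MT1X rose (2 adjusted over the list alone; camera adjusted p = 0.0133, and adjusted p = 0.193 with an estimated correlation). MT1G had a log2 fold change of 0.75 ± 0.32 and did not pass (adjusted p = 0.133). Among 20 selenoproteins, 3 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.439). The risers were TXNRD1, SEPHS2 (0.32 ± 0.05) and SELENOK (0.19 ± 0.06), and the deiodinase gene DIO2 fell by 0.89 ± 0.13. Heat shock chaperones did not pass as a list (camera adjusted p = 0.140, and 0.0292 with fry): of 19, DNAJB1 rose by 0.22 ± 0.06 and HSPB1 fell by 0.40 ± 0.12, and adjusted over the list alone the 1 call was DNAJB1. SELENOK and HSPB1 were named after their values were seen. Their calls were lost without DMSO replicate 2 (adjusted p = 0.141 and 0.0940), DMSO replicate 3 (0.154 and 0.101) and AF replicate 3 (0.121 and 0.0837), and other single libraries also ended them. That of DNAJB1 was lost without DMSO replicate 2 (0.0726), DMSO replicate 3 (0.0677) or AF replicate 1 (0.0709).

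Genes of the cholesterol supply under SREBP2 rose, while the cholesterol exporters ABCA1 and ABCG1 fell. In the SREBP2 list 11 of 24 tested members rose (0 with library totals alone; 13 higher and 1 lower, PMVK, adjusted over the list alone), with a median log2 fold change of 0.24 (camera adjusted p = 3.2e-05; adjusted p = 0.0416 with an estimated correlation). With an estimated correlation the list did not pass when any one library was left out (0.0628 without DMSO replicate 2 to 0.127 without DMSO replicate 3), nor with protein-coding genes alone (0.104). STARD4, a sterol carrier gene, rose by 0.52 ± 0.08 and DHCR7, of the last step of cholesterol synthesis, by 0.47 ± 0.06. Without AF replicate 1 the list had 11 members higher and 1 lower. Of 13 fatty acid synthesis genes under SREBP1, 6 rose (8 higher and 1 lower, FASN, adjusted over the list alone; camera adjusted p = 0.00342; adjusted p = 0.148 with an estimated correlation, and 0.0518 with library totals alone, where 0 members were called). They included the desaturase genes FADS1 (0.56 ± 0.06), FADS2 (0.46 ± 0.07) and SCD (0.36 ± 0.06). The list of cholesterol efflux and LXR targets did not pass (camera adjusted p = 0.470): of 15 members, 3 rose and 2 fell, as they did adjusted over the list alone. CYP27A1, a sterol hydroxylase gene, rose by 0.85 ± 0.09, the lysosomal cholesterol transporter gene NPC1 by 0.31 ± 0.06 and NR1H3, which encodes LXR alpha, by 0.31 ± 0.10. NR1H3, PMVK and FASN were named after their values were seen. ABCG1 fell by 0.42 ± 0.06, from 73.6 ± 3.27 to 55.1 ± 4.57 CPM, and ABCA1 by 0.26 ± 0.07, from 408 ± 14.97 to 341 ± 26.9 CPM. The ABCA1 call was lost without DMSO replicate 3 (adjusted p = 0.0600), AF replicate 2 (0.0597) or AF replicate 3 (0.0690), and the NR1H3 call without any of 6 libraries, for example AF replicate 3 (0.157).

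Some receptors and carriers of modified lipoprotein uptake fell, while 9 of the 14 tested were not called. Of 14 tested, 5 fell (3 with library totals alone; 1 higher, CXCL16, and 6 lower adjusted over the list alone), with a median log2 fold change of -0.20 (camera adjusted p = 0.0130; adjusted p = 0.385 with an estimated correlation, and 0.0529 without AF replicate 3). MSR1, the scavenger receptor for acetylated LDL, fell by 0.73 ± 0.12, from 213 ± 11.8 to 128.5 ± 30.5 CPM. The fatty acid binding protein genes FABP4 and FABP5 fell by 0.50 ± 0.13 and 0.33 ± 0.10, and the scavenger receptor genes COLEC12 and STAB1 by 0.31 ± 0.07 and 0.37 ± 0.12. CD36 did not pass, with a log2 fold change of -0.17 ± 0.12 (adjusted p = 0.376); without AF replicate 4 it was -0.34 (adjusted p = 0.00465). In libraries 1 and 4 alone the list median was -0.01 (camera adjusted p = 0.538) and in libraries 2 and 3 alone -0.37 (0.000255). For storage of cholesteryl esters and lipid droplets, 2 of 15 genes rose and 1 fell (4 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.460, and 0.0207 with fry; its median, -0.001, and its mean, 0.10, differ in sign). CES1, an ester hydrolase gene, rose from 117 ± 7.47 to 298 ± 33.8 CPM (1.35 ± 0.08), and its pseudogene may share its reads. G0S2, a lipase inhibitor gene, rose by 0.55 ± 0.09, and the droplet coat gene PLIN2 fell by 0.35 ± 0.09. SOAT1, which encodes the esterifying enzyme, had a log2 fold change of 0.19 ± 0.06 (adjusted p = 0.0596), and 0.23 without DMSO replicate 4 (adjusted p = 0.0259). The call of PLIN2 was lost without DMSO replicate 2 (adjusted p = 0.0718), DMSO replicate 3 (0.0677), AF replicate 2 (0.0605) or AF replicate 3 (0.0792), and that of FABP4 without AF replicate 3 (0.0555). In libraries 1 and 4 alone PLIN2, FABP4 and FABP5 had log2 fold changes of -0.10, -0.25 and -0.07. In libraries 2 and 3 alone these were -0.61, -0.82 and -0.62. CXCL16 was named after its values were seen. FABP5 and STAB1, also named after their values were seen, were lost without DMSO replicate 2 (0.0874 and 0.130) and 4 or 5 other single libraries.

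**Figure D3:**
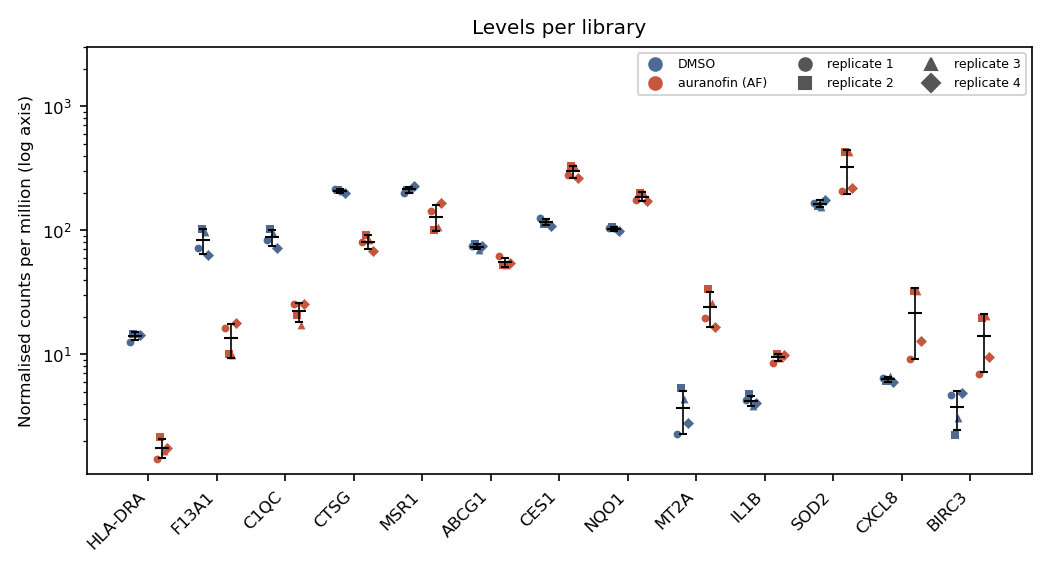
Normalised CPM (log axis) of 13 genes in each library (DMSO blue, auranofin red, a marker shape per replicate), with group means and SD as black bars. CXCL8, BIRC3 and SOD2 were higher in AF replicates 2 and 3 than in AF replicates 1 and 4, while IL1B lay between 8.5 and 10.0 in the 4 AF libraries.

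Inflammatory cytokines and NF-kB targets rose: 17 of 24 tested members were higher (17 adjusted over the list alone, 16 without AF replicate 1, and 10 with library totals alone), with a median log2 fold change of 0.63 (camera adjusted p = 1.8e-06; adjusted p = 0.222 with an estimated correlation). IL1B, an inflammasome cytokine gene, rose from 4.21 ± 0.387 to 9.44 ± 0.666 CPM (1.16 ± 0.11). CCL2, a monocyte chemokine gene, did not pass, with a log2 fold change of -0.03 ± 0.18 (adjusted p = 0.936), and turned positive without DMSO replicate 2 (0.17) or AF replicate 4 (0.013). The AF libraries differed in this group: SOD2, named after its values were seen, stood at 208, 429, 428 and 218 CPM in AF replicates 1 to 4, against 155 to 176 in DMSO. The list median was 0.29 in libraries 1 and 4 alone and 0.93 in libraries 2 and 3 alone. Interferon-stimulated genes moved the opposite way. Of 27 tested 11 fell (13 adjusted over the list alone, and 11 without AF replicate 1, when 1 rose), with a median of -0.32 (camera adjusted p = 7.0e-05; adjusted p = 0.0416 with an estimated correlation). With an estimated correlation this list too was lost when any one library was left out (0.0628 without DMSO replicate 2 to 0.114 without DMSO replicate 3), and with protein-coding genes alone (0.0904). The antiviral genes MX1 and RSAD2 fell by 1.48 ± 0.15 and 1.24 ± 0.18, and OAS3 by 0.71 ± 0.09.

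The integrated stress response list rose and the cell cycle list fell. Of 21 genes of the integrated stress response, 11 rose (11 adjusted over the list alone, 11 without AF replicate 1, and 3 with library totals alone; median 0.29; camera adjusted p = 5.5e-06; adjusted p = 0.385 with an estimated correlation). They included DDIT4 (0.92 ± 0.10), DDIT3 (0.80 ± 0.10) and PPP1R15A (0.55 ± 0.08). The median of this list was 0.20 in libraries 1 and 4 alone (camera adjusted p = 0.000545, 4 members called). In libraries 2 and 3 alone it was 0.42 (camera adjusted p = 1.6e-08, 16 members called). Of 16 endoplasmic reticulum chaperones and their regulators, 6 rose and SDF2L1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00236; adjusted p = 0.168 with an estimated correlation, and 0.0518 with library totals alone, where 0 members were called), with a median of 0.14 that turned to -0.01 with library totals alone. HERPUD1 rose by 0.58 ± 0.10, XBP1 by 0.48 ± 0.07 and MANF by 0.32 ± 0.06. Of 25 cell cycle genes 12 fell and 1 rose (13 and 2 adjusted over the list alone, and 10 and 1 without AF replicate 1; median -0.18; camera adjusted p = 0.00013; adjusted p = 0.127 with an estimated correlation). The replicative helicase genes MCM2, MCM3 and MCM4 fell by 0.57 ± 0.09, 0.56 ± 0.06 and 0.58 ± 0.08, whereas the mitotic cyclin gene CCNB1 rose by 0.22 ± 0.05. Of 15 p53 targets, TNFRSF10B (1.03 ± 0.09), GDF15 (0.66 ± 0.14) and PMAIP1 (0.57 ± 0.13) rose (5 higher and 1 lower, BAX, adjusted over the list alone), and the list did not pass (camera adjusted p = 0.141, and 0.0356 with library totals alone, when its median was -0.07). BAX was named after its values were seen. Of 25 genes of glycolysis and hypoxia, 7 rose and TPI1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.180, and 0.0207 with fry), with NDRG1 at 0.73 ± 0.07 and VEGFA at 0.60 ± 0.11. The call of SDF2L1 (-0.29 ± 0.09) was lost without DMSO replicate 1 (adjusted p = 0.0775), DMSO replicate 2 (0.148), DMSO replicate 3 (0.158), AF replicate 3 (0.141) or AF replicate 4 (0.0878), and that of CCNB1 without DMSO replicate 2 (0.0523).

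Protein-coding transcripts of the mitochondrial genome fell: 10 of 13 were lower (12 adjusted over the list alone, 12 without AF replicate 1, and 4 with library totals alone), with a median of -0.36 (camera adjusted p = 7.2e-08; adjusted p = 0.193 with an estimated correlation). MT-CYB, a respiratory complex subunit gene, fell from 861 ± 89.3 to 516 ± 38.9 CPM (-0.74 ± 0.09). These protein-coding transcripts made up 1.1% of all counts in AF replicate 1, which was rich in ribosomal RNA, 1.76% to 2.00% in the other AF libraries and 2.11% to 2.52% in DMSO. The 2 ribosomal RNA genes of that genome, named after their values were seen, rose: MT-RNR1 by 1.58 ± 0.50 and MT-RNR2 by 0.56 ± 0.18 (adjusted p = 0.0439 and 0.0463, edgeR). AF replicate 1 carried most of this, with 3391 CPM of MT-RNR1 against 479 to 550 in the other AF libraries and 392 to 444 in DMSO. Without it the log2 fold changes were 0.30 and 0.25 (adjusted p = 0.00637 and 0.00785). Both calls were lost when any one DMSO library was left out, for example DMSO replicate 2 (0.101 and 0.119), and that of MT-RNR2 with DESeq2 (0.150) and with library totals alone (0.442). With a block by replicate number the call of MT-RNR1 was lost (0.0895). Cytosolic ribosomal proteins passed the set test (camera adjusted p = 0.00561; adjusted p = 0.567 with an estimated correlation, 0.119 without DMSO replicate 3 and 0.225 with fry), with a median of -0.09, and of 38 members RPS2 alone was called (1 adjusted over the list alone; -0.35 ± 0.09). Without AF replicate 1, 11 were called lower, and without DMSO replicate 3 the adjusted p of RPS2 was 0.0527. In libraries 1 and 4 alone the list did not pass (median -0.01, 0 members called, camera adjusted p = 0.585). In libraries 2 and 3 alone its median was -0.18, with 24 members called lower. RPS2 has processed pseudogenes that can take its reads. Of 31 proteasome subunits PSMC3 (-0.32 ± 0.07) and PSMA7 (-0.17 ± 0.05) fell (1, PSMC3, adjusted over the list alone), and the list did not pass (camera adjusted p = 0.447). PSMA7, named after its values were seen, was not called without DMSO replicate 2 (adjusted p = 0.105) or without any of 5 other single libraries.

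The lists of MHC class II presentation, macrophage differentiation and myeloid progenitor genes fell, while those of lysosomal genes and matrix proteases rose. For MHC class II, HLA-DRA, HLA-DPB1 (-2.96 ± 0.31), HLA-DPA1 (-2.28 ± 0.32) and CD74 (-0.86 ± 0.08) fell among 10 tested (4 adjusted over the list alone, and 4 without AF replicate 1; camera adjusted p = 0.000131; adjusted p = 0.0995 with an estimated correlation). HLA-DPB1 and HLA-DPA1 were low in both groups, with means of 1.53 and 1.77 CPM in DMSO and 0.19 and 0.35 CPM with auranofin. HLA-DRB1 stood at 207 ± 17.7 CPM in DMSO and 197 ± 12.5 with auranofin (-0.08 ± 0.07, adjusted p = 0.497); it and HLA-DPA1 were named after their values were seen. Of 18 macrophage differentiation markers 8 fell and 4 rose (9 and 5 adjusted over the list alone; camera adjusted p = 0.0487; adjusted p = 0.445 with an estimated correlation). This list did not pass without DMSO replicate 1 (0.0520), 2 (0.0853) or 3 (0.0766) or AF replicate 2 (0.0621), 3 (0.0614) or 4 (0.0868), nor with libraries summed by name stem (0.0567). C1QA fell by 1.36 ± 0.11, and the integrin genes ITGAX and ITGAM rose by 0.69 ± 0.09 and 0.43 ± 0.07, MERTK by 0.39 ± 0.07 and CD14 by 0.33 ± 0.10. Of 10 markers of alternative activation, F13A1, MRC1 (-1.50 ± 0.16), FOLR2 (-1.31 ± 0.16) and MAF (-0.62 ± 0.05) fell and CCL22 (0.52 ± 0.15) and TGM2 (0.40 ± 0.09) rose (4 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.165). It passed with library totals alone (0.0191), with libraries summed by name stem (0.0207), with no filter on low counts (0.0037) and with fry (0.00319). Of 14 progenitor and granule genes 6 fell and 2 rose (9 and 2 adjusted over the list alone, and 7 and 1 without AF replicate 1; camera adjusted p = 0.000568; adjusted p = 0.148 with an estimated correlation). The progenitor transcription factor gene MYB fell by 1.37 ± 0.12, the granule protease gene CTSG by 1.36 ± 0.08 and lysozyme, LYZ, by 0.95 ± 0.09, whereas S100A9 and S100A8 rose by 0.55 ± 0.09 and 0.31 ± 0.09. ITGAM, MERTK, CD14, FOLR2, CCL22 and S100A8 were named after their values were seen. CD14, CCL22 and S100A8 were not called without AF replicate 1 (adjusted p = 0.0522, 0.0736 and 0.0800) or any of 4 or 5 other single libraries.

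Of 23 lysosomal genes 7 rose (10 adjusted over the list alone, and 8 without AF replicate 1; camera adjusted p = 0.00132; adjusted p = 0.0995 with an estimated correlation, and 0.0880 with library totals alone, where 0 members were called), with a median of 0.13 that turned to -0.01 with library totals alone. The cathepsin genes CTSD and CTSL rose by 0.43 ± 0.09 and 0.32 ± 0.06 and LAMP1 by 0.31 ± 0.06. Of 12 matrix proteases and inhibitors MMP19 (0.45 ± 0.10), MMP9 (0.41 ± 0.07) and ADAM17 (0.20 ± 0.05) rose (3 adjusted over the list alone; camera adjusted p = 0.0166; adjusted p = 0.222 with an estimated correlation, 0.0880 with library totals alone, where 0 members were called, and 0.0766 with libraries summed by name stem), with a median of 0.13 that turned to -0.02 with library totals alone. In libraries 1 and 4 alone this list did not pass (camera adjusted p = 0.199, 0 members called), while in libraries 2 and 3 alone it did (0.00866). ADAM17 was not called without DMSO replicate 3 (adjusted p = 0.0717) or AF replicate 3 (0.0885). Of 8 dendritic cell and osteoclast markers, CD83 (0.47 ± 0.12) and DCSTAMP (0.61 ± 0.20) rose and CD209 (-0.59 ± 0.06) and CD1C (-0.97 ± 0.24) fell (2 and 3 adjusted over the list alone, with CD1A, named after its values were seen; camera adjusted p = 0.534). CD83 was not called without AF replicate 3 (0.0510), CD1C (-0.23 in libraries 1 and 4 alone and -1.58 in libraries 2 and 3 alone) without DMSO replicate 3 (0.0529), and DCSTAMP, named after its values were seen, without DMSO replicate 2 (0.150) or any of 4 other single libraries. Lists of lymphocyte, fibroblast and endothelial, and epithelial markers did not pass (camera adjusted p = 0.259, 0.439 and 0.267; the first had 0.0151 with fry). Their called members were CD5 (-1.41 ± 0.41) of 5 tested, COL3A1 (-1.71 ± 0.41) of 6 and CLDN7 (0.65 ± 0.15) of 2, as they were adjusted over the list alone. CD5 lay below 1 CPM on average and was not called without DMSO replicate 3 (0.132), DMSO replicate 4 (0.0546), AF replicate 3 (0.100) or AF replicate 4 (0.0581). Of 4 reported key drivers of a foam cell gene network, 0 were called by edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 by DESeq2; camera adjusted p = 0.397), and the smallest p was that of DRAP1 (-0.17 ± 0.09).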

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

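The test of ribosomal RNA in AF replicates 2 to 4 was chosen after its result had been seen. Of 272 groups of 4 values examined for a library far from the rest, 7 stood out. Chance alone would give 13.6, but many of the groups are genes named for a small p or for no overlap between groups. Such a choice disfavours an outlying library, so these numbers cannot be compared. All 7 were AF replicate 1. The measure is the gap to the nearest library as a share of the group's range. Ribosomal RNA was 34.8% of its counts against 0.809% to 0.852% in the other AF libraries (0.999), and RN7SL1, a signal recognition particle RNA, 1450 CPM against 33.3 to 58.3 (0.982). RMRP, an RNA of a ribonuclease complex, stood at 109 CPM against 0.790 to 1.36 (0.995), protein-coding genes at 59.4% against 91.2% to 91.6% (0.989) and pseudogenes at 3.63% against 5.49% to 5.84% (0.843). The mitochondrial ribosomal RNA genes MT-RNR1, 3391 CPM against 479 to 550 (0.976), and MT-RNR2, 8713 CPM against 4341 to 4785 (0.899), were added to the groups after their values were seen. RN7SL1 and RMRP were also named after their values were seen.

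A drug effect on the ribosomal RNA share of the libraries is argued against by the other AF libraries, whose mean of 0.837% ± 0.0242 (SD, n = 3) lay below the highest DMSO library, 0.963%. After poly-A selection this share cannot tell how much ribosomal RNA the cells held. Incomplete poly-A selection of this library may explain the pattern but was not settled: the median log2 ratio of 21 histone genes, whose messages carry no poly-A tail, to AF replicates 2 to 4 was 0.83, short of the bound of 1 set beforehand and above 0.5, the bound for the opposite. Of the 21, 20 lay above 0. No biological explanation other than the drug was tested.

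Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many as the 2705 genes called. The other splits mix AF and DMSO libraries, so any difference between the groups enters their spread and holds down their calls. A share of 1 in 35 is the smallest possible, so this ranking alone cannot exclude a chance division. This says nothing of separate cultures. The highest of the other 34 splits was 0 (edgeR), with 169 to 2812 genes at an unadjusted p under 0.05, against 5216 in the real split.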

How the results depend on the processing

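All alternatives were fixed before the data were examined, except protein-coding genes alone and those that divide the libraries into 1 and 4 against 2 and 3. Of 95 genes named by the rule 88 were called, and these 88 kept their direction in the 28 alternatives; 77 stayed called whichever library was left out. Against 2705 genes called in the main fit, other settings called 883 with library totals alone (named genes called: 48), where the ribosomal RNA of AF replicate 1 enters the scaling, 4188 with a replicate block, 4593 with AF libraries summed by name suffix, 859 without stem A4, 1181 without stem A5 and 1794 without stem A14. Libraries 1 and 4 summed and 2 and 3 summed gave 1105, libraries 1 and 4 alone 212 (named genes called: 40) and libraries 2 and 3 alone 5354. The fit of libraries 1 and 4 alone holds AF replicate 1, which was rich in ribosomal RNA. A block of libraries 1 and 4 against 2 and 3 gave 3483. Leaving out each library gave 1616 (DMSO replicate 2) to 2964 (AF replicate 4), and for 2-fold changes 250 to 386. Against 316 genes changed at least 2-fold, other settings gave 499 with no filter on low counts, 201 without stem A5, 76 in libraries 1 and 4 alone and 637 in libraries 2 and 3 alone. The cause was not tested. With an estimated correlation 2 of the 17 lists passed, and 0 without AF replicate 1.

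The replicate numbers were not taken to pair the libraries, since correlations of same-numbered deviations were 0.09, 0.13, 0.03 and 0.19, and 2 of the 4 exceeded 0.1. Of the 8 libraries 6 correlated best with their own number, a hint from the data and not the design. With the replicate block SOAT1 was called (adjusted p = 0.00905), and the macrophage differentiation list did not pass (adjusted p = 0.163). PMVK (0.00649), FASN (0.00692), BAX (0.0204) and CXCL16 (0.0475) were also called with that block, and MT-RNR1 (0.0895) was not. CCL2 (-0.03) reversed to 0.011 with limma voom, 0.080 without stem A4, 0.046 without stem A14 and 0.16 in libraries 1 and 4 alone, and ranged from -0.14 to 0.17 as each library was left out (0.013 without AF replicate 4, 0.17 without DMSO replicate 2). CD36 (-0.17) was 0.0088 in libraries 1 and 4 alone. The cause was not tested. In simulated counts 16% of genes changed by the smallest size tried were recovered. Far fewer genes were called there than in the data, so the adjusted threshold was stricter and this share may not carry over.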

Other observations

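The tests on ribosomal RNA in AF replicate 4, on NF-kB targets in DMSO and on LXR targets were chosen after their results had been seen, as were the 6 genes named next. DUSP1, a phosphatase gene of MAP kinase signalling, rose by 1.54 ± 0.10 on the log2 scale (SE), the transcription factor gene SNAI1 by 1.48 ± 0.13 and the matrix glycoprotein gene THBS1 by 1.47 ± 0.13. Falls had log2 fold changes of -1.40 ± 0.06 for the lectin gene SIGLEC1, -1.29 ± 0.12 for TLR7, a sensor of single-stranded RNA, and -0.85 ± 0.08 for the fractalkine receptor gene CX3CR1. The adjusted p was 1.01e-05 or less for each of these 6 genes (edgeR).

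The ferritin genes FTH1 and FTL, also named after their values were seen, rose by 0.70 ± 0.13 and 0.53 ± 0.09, and 13 of 15 FTH1 pseudogenes rose with a median log2 fold change of 1.09. Reads shared with the parent gene may account for the direction of these changes. The pseudogene median exceeded the rise of FTH1 itself, and this excess was not explained. Of 140 called pseudogenes with a tested parent gene, 129 (92.1%) moved in the parent's direction, over the bound of 80% set before the result was seen. The 140 pseudogenes had 80 parent genes, and 48 were ribosomal protein pseudogenes, of which 47 fell, so they are not independent of one another. Transcription of the pseudogenes themselves was not tested.

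NF-kB targets were higher in AF replicates 2 and 3 than in AF replicates 1 and 4. The median log2 ratio to AF replicates 2 and 3 over the 17 called members was -0.64 in AF replicate 1 and -0.74 in AF replicate 4. For AF replicate 4 ribosomal RNA is argued against, since its share, 0.852%, lay below the highest DMSO library, 0.963%. For AF replicate 1, at 34.8%, it stays open. Vehicle-treated material in AF replicate 4 is argued against too: the median member would need 75.3% of it, and HLA-DRA allows at most 16.7%. That limit is a 95% upper bound from 45 HLA-DRA counts. It covers counting error alone and takes reads as independent molecules. A batch that shifts these genes alike in both groups is argued against as well, since DMSO replicates 2 and 3 stood to DMSO replicates 1 and 4 at a median log2 ratio of -0.14 (quartiles -0.27 and 0.03), against 0.68 (0.25 and 1.01) in AF. Whether libraries 2 and 3 of both groups share a batch at all was not settled: over genes outside the list, the difference between these pairs correlated across genes between DMSO and AF with r = 0.158, while dividing the libraries into 1 and 2 against 3 and 4 gave 0.189; genes are not independent replicates. Replicates 2 and 3 were the closest pair in each group, with a chi-square per degree of freedom of 2.96 in DMSO and 4.49 in AF. This goes with a shared batch, but the correlation did not single out that division. A batch that acts only on the response to the drug, or a difference in the response of separate cultures, was not tested.

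A hypothesis for the rise of SREBP2 targets beside the fall of ABCA1 and ABCG1 is that less sterol may have reached the LXR receptors. It predicts that the other LXR targets fell. The list tested holds cholesterol efflux genes as well as LXR targets, so it bears on this prediction only in part. Over its other 13 members, fixed before the data were examined, the mean log2 fold change was 0.05 ± 0.08 (SE across genes), the median was -0.05, and 10 members lay below 0. fry gave p = 0.362, and an exact permutation test of the mean over the 70 assignments of the libraries, two-sided, p = 0.229, so the data did not decide. A first version of this test used 7 members picked after their values were seen, all 7 below 0, and gave p = 0.0360 with fry and p = 0.0286 in the exact permutation test, the smallest it can give. It left out CYP27A1, NPC1 and NR1H3 (the last named after its values were seen), which rose, and 3 other members, and carries no weight.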
